A study of Mus musculus with 8 samples.

How the data were processed

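Total RNA of frozen cerebellum from 8 C57BL/6JN mice was extracted with Trizol and column purification with DNase digestion, per the labels' protocols. About 700 ng went into libraries of a ribosomal RNA depletion kit for total RNA (Zymo-Seq RiboFree). The sample labels give the tissue as cerebellum and ages of 19 to 22 and 83 to 102 weeks, while the series' design text names another tissue, liver, and other age ranges, so tissue, age and sex were taken from the sample labels. The design text calls the samples of a group biological replicates.

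The authors deposited 1 table per library holding raw counts per gene, with no normalization, per the file headers and the values, which are whole numbers with different totals. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic 0.39, FastQC 0.11.9, STAR 2.7.5b, SAMtools 1.10, Picard 2.20.8, deepTools 3.5.0 and featureCounts, and the builds GRCm38 and mm10. The gene annotation, the strand setting and the treatment of reads mapping to several places are not given in the sources used here, so overlapping, antisense and near-identical genes may share reads. The deposited tables list 17700 genes, each with 2 or more counts over the 8 libraries, and 17562 of the 17587 that matched the GENCODE M21 annotation of GRCm38 by symbol are protein-coding. Mitochondrially encoded genes and Xist were not analysed here. Spreadsheet-style dates stood in place of 24 gene names in 7 of the 8 tables, and the tables were joined by row with the names of the table that keeps them. Coordinates are from GENCODE M21 (GRCm38).

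Counts totalled 6079485 to 7236720 per library. No pair of libraries agreed within sampling noise. Genes were kept by edgeR's filterByExpr with its minimum of 10 counts over the 4 age-by-sex cells, which left 14191. Libraries were scaled with TMM, and log2 CPM values use a prior count of 2. The main test was edgeR 4.0.16 (R 4.3.3) quasi-likelihood with robust dispersions, on a model with age and sex, using all 8 libraries. Its newer dispersion method was used, because the older one, which this version runs unless told otherwise, had been listed as an alternative. Log2 fold changes are old minus young or female minus male, standard errors were taken as the absolute log2 fold change over the square root of F, and p-values were adjusted by Benjamini-Hochberg over all genes tested with a threshold of 0.05. The interaction of age and sex was tested in a fit of the 4 cells of 2 animals.

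The gene lists, the rule for named genes, the tests and most alternatives were set before the data were examined. There were 42 lists of cell type markers, pathways and complexes, of which 39 had at least 5 tested genes. Camera (limma 3.58.1) tested each with a preset correlation of 0.01 between genes, and again with an estimated correlation, and fry was run beside it. Camera compares a list with the other genes, while fry asks whether its genes move, on balance, one way. A list's score in a library is the median deviation of its genes' log2 CPM from their mean over the 8 libraries, and old and young scores were compared by exact two-sided permutation over 70 regroupings. Genes named for age were those past the threshold with a mean log2 CPM of at least 1 and no overlap between old and young values, up to 12 each way, leaving out unnamed gene models. Further named genes were up to 4 members of each list with the smallest p, the DNA methylation and hydroxymethylation genes tested, up to 5 genes each way for sex and up to 4 for the interaction, Nnt and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Of the 17 genes past the threshold for age, Itgax and Cd52 fell below the level minimum and are named as list members, and Prl is named under the rule for sex. Some genes that the rule takes in are not reported here.

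Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no filter on low counts, a filter of 50 counts in 4 libraries, the older edgeR dispersions, no term for sex or for age, the replicate number as a block, 1 surrogate variable (sva 3.50.0), age in weeks, a fold change of at least 1.5, the estimated correlation and each library left out. Added after seeing the data were a GC correction (lowess of each library's deviations on transcript GC content, span 0.3), the choroid plexus score or the granule neuron score as a covariate, and a fit without old 2, old 3 and young 4. The tests were run on simulated counts with 200 changed genes drawn at the measured means, depths and dispersions. For age 40.3% of genes changed 1.5-fold, 76.1% changed 2-fold and 98.5% changed 4-fold were recovered among 14052 genes, for sex 53.7%, 77.6% and 97.0% among 14040, and for the interaction 3.0%, 28.4% and 75.8% among 14044. A list raised 2-fold in the simulation was called and no other list was. Each gene was drawn independently, so the simulation could not show false list calls that arise when genes move together. The simulated age comparison called 152 genes, against 17 in the real libraries, where the adjusted threshold was therefore stricter. The recovered shares may be too high for the real libraries.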

Results

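RNA of the cerebellum, the hindbrain region that holds granule neurons, Purkinje cells and Bergmann glia, was sequenced from 8 C57BL/6JN mice. The old group held 4 mice of 83 to 102 weeks and the young group held 4 mice of 19 to 22 weeks, with 2 males and 2 females at each age. Each library came from a separate animal, so the spread between libraries includes the spread between mice. Total gene counts were 6132312, 6784584, 6401932 and 6183862 in old 1 to old 4, and 6518897, 6413457, 6079485 and 7236720 in young 1 to young 4. At these depths 3 counts of a gene corresponded to 0.421 to 0.511 CPM, counts scaled to the TMM-adjusted total of the library, and this floor covers counting error only. Of 17700 listed genes, 14191 had enough counts to be tested.

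The libraries differed within each age in the levels of liver, choroid plexus and granule neuron transcripts. Scaled to unadjusted library totals, the 7 liver genes Alb, Apob, Apoa1, Apoa2, Fga, Fgb and Ahsg summed to 86.2 CPM in old 2, 23.4 CPM in old 3 and 20.9 CPM in young 4, against 0.658 to 9.78 CPM in the other 5 libraries. Ttr, the transthyretin transcript of choroid plexus epithelium, was at 1.57 CPM in old 3, 5.45 CPM in young 3 and 2.39 CPM in young 4, and between 149 and 422 CPM in the other 5 libraries. These liver genes and Ttr were singled out after their values were seen. The score of the granule neuron markers, the median deviation of their log2 CPM from the mean of the 8 libraries, was -0.35 in old 4, -0.24 in young 2, -0.15 in old 1 and -0.06 in young 3. It was 0.01 in old 2, 0.14 in old 3, 0.28 in young 1 and 0.38 in young 4.

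**Figure D1:**
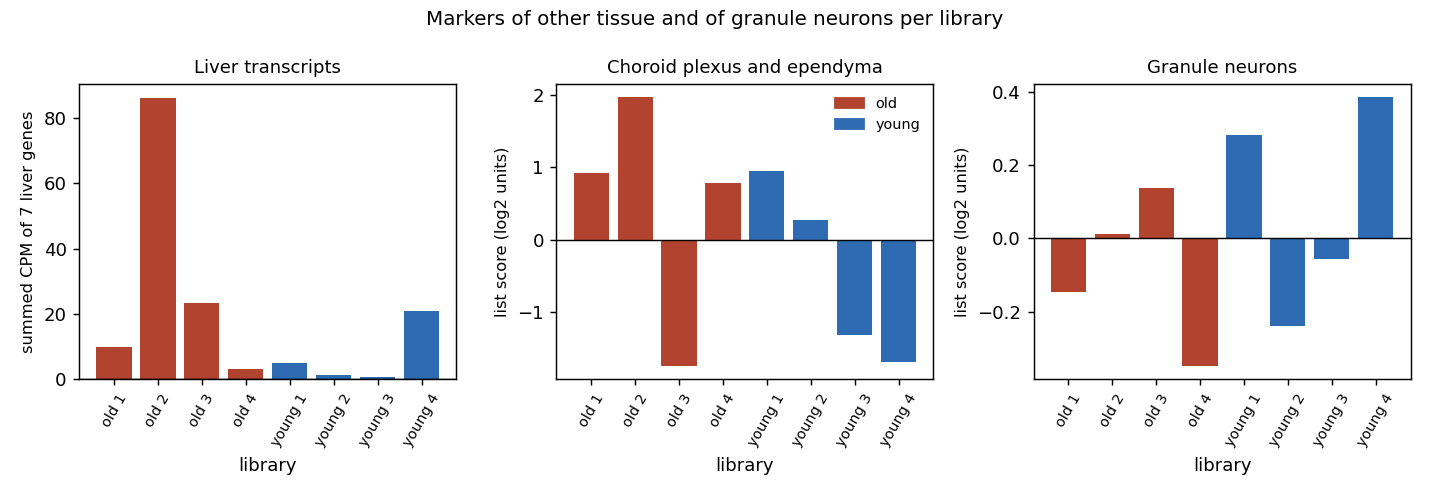
Bars give, per library, the summed CPM of 7 liver genes on the left, and the scores in log2 units of the choroid plexus and ependymal markers and of the granule neuron markers in the middle and on the right, with old libraries in red and young libraries in blue. Liver transcripts were highest in old 2, at 86.2 CPM, and the choroid plexus score ran from -1.73 in old 3 to 1.97 in old 2.

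The comparison of old with young cerebellum asked how transcript levels change with age, in a study whose title relates the size of such changes to DNA hydroxymethylation within genes. The genes that rose in old cerebellum past edgeR's test included genes of interferon responses, antigen presentation and innate immunity. C3, the central complement component, had 19.6 ± 13.3 CPM (SD, n = 4) in old and 2.68 ± 2.49 CPM (SD, n = 4) in young mice, a log2 fold change of 2.83 ± 0.38 (SE). H2-Q6 and H2-Q7, neighbouring MHC class I genes, rose by 2.65 ± 0.36 and 2.18 ± 0.33 on the log2 scale. The interferon-induced genes Ifit1 and Bst2 rose by 1.92 ± 0.26 and 1.49 ± 0.22, and the beta protocadherin Pcdhb14, a neuronal adhesion gene, rose by 0.76 ± 0.08. Tnc, the extracellular matrix glycoprotein tenascin C, and Fabp7, a fatty acid binding protein of astroglia, fell by 1.15 and 0.82 on the log2 scale, with SE of 0.17 and 0.12.

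In all, 17 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a term for sex, 14 higher and 3 lower in old mice. The 14 also included the interferon-inducible GTPases Gbp5, Igtp and Irgm1, with log2 fold changes of 1.58 ± 0.26, 1.30 ± 0.21 and 1.01 ± 0.14. Zc3hav1, an antiviral zinc finger protein, rose by 0.95 ± 0.13 and the gamma protocadherin Pcdhgb4 by 0.62 ± 0.10. Itgax, which encodes the integrin CD11c, rose by 4.04 ± 0.53 from 0.159 ± 0.140 CPM (SD, n = 4) in young to 2.86 ± 1.42 CPM (SD, n = 4) in old mice. Cd52, a leukocyte surface antigen, rose by 2.92 ± 0.42. The young mean of Itgax lay below the floor of 3 counts, 0.421 to 0.511 CPM. Young Cd52 values were also low, at log2 CPM of -1.11 to -0.28, so the sizes of both rises are uncertain. The third gene that fell was Adgrb2, an adhesion G protein-coupled receptor, by 0.55 on the log2 scale with SE 0.08. The 4 old and the 4 young values did not overlap for 16 of the 17 genes. The exception was the prolactin gene Prl, with 52 and 37 counts in old 2 and old 4, both females, and 2 counts or fewer in each other library. Its ratio of old to young was 29.9, with a 95% exact counting interval of 9.92 to 148, from 90 counts in old and 3 in young mice. That interval covers counting error only and not the spread between mice. Prl is a gene of the anterior pituitary. Gh, another such gene, had 12 and 9 counts in old 2 and old 4, but 69 in old 1, where Prl had 1. Whether the Prl counts came from cerebellar cells was not tested.

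C3 lies on chromosome 17 at 57203970 to 57228136 in GRCm38, Ifit1 on chromosome 19 at 34640871 to 34650009, Tnc on chromosome 4 at 63959785 to 64047015 and Fabp7 on chromosome 10 at 57784881 to 57788450. Itgax lies on chromosome 7 at 128129547 to 128150657. H2-Q6 and H2-Q7 lie on chromosome 17 at 35424850 to 35430055 and 35439155 to 35443773, and Pcdhb14 on chromosome 18 at 37447656 to 37456350. Pcdhgb4, at 37720369 to 37841870 on chromosome 18, shares its 3' exons with the other gamma protocadherins. These are whole gene spans, and the counts cover each gene as a unit. Reads may be split among near-identical copies, so the values of H2-Q6, H2-Q7 and Pcdhgb4 are uncertain as to which member of their cluster they come from.

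**Figure D2:**
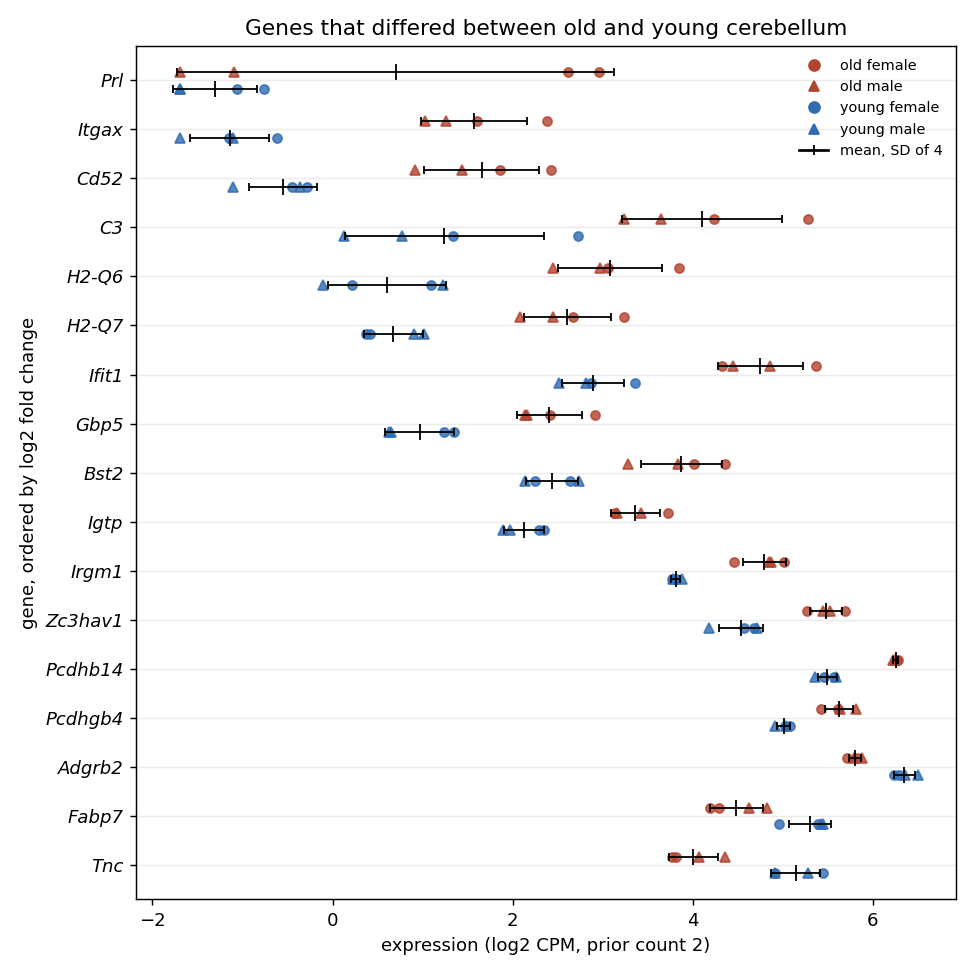
Expression in log2 CPM of the 17 genes that differed between old and young mice, ordered by log2 fold change, with 1 point per library (circles for females, triangles for males) and bars for the mean and SD of 4 libraries. The old and young points are apart for each gene except Prl, whose 2 high points are the old females.

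Without young 3, or without young 4, no gene passed, 2 passed without old 1 or without young 1, 8 without young 2, 13 without old 4 (7 of the 17 among them), 49 without old 3 and 63 without old 2. The count was 1 by limma-voom, 125 by DESeq2, 9 with the choroid plexus score and 154 with the granule neuron score as a covariate. It was 184 without the 3 libraries richest in liver transcripts, with old 1 and old 4 left against young 1, young 2 and young 3. The granule neuron scores of the libraries left out were 0.01, 0.14 and 0.38. Liver transcripts are therefore not singled out by this fit. Each of the 17 genes kept its direction wherever it was tested. They were selected on these same libraries, so the kept direction is no independent support.

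The interferon-stimulated genes had the largest median shift of the lists and the smallest p by camera's preset test. All 25 tested members had positive log2 fold changes, with a median of 1.38, and 24 passed when adjusted over the list alone, against 2 over all genes tested. Ifi27 and Gbp3 had log2 fold changes of 1.02 ± 0.17 and 1.06 ± 0.18 beside those of Ifit1 and Bst2. Of the 15 MHC class I antigen presentation genes, 14 had positive values, with a median of 0.98, and 12 passed adjusted over the list alone, against 2 over all genes. H2-K1, a classical class I heavy chain, had 85.9 ± 28.8 CPM (SD, n = 4) in old and 37.4 ± 3.25 CPM (SD, n = 4) in young mice, and B2m, the class I light chain, 51.0 ± 11.4 and 27.2 ± 8.87 CPM. Both lists were higher in old mice by camera with its preset correlation, and neither call held with an estimated correlation, where the adjusted p = 0.164 for each. In both lists each of the 4 old library scores lay above each of the 4 young ones (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give, and 0.186 after adjustment over 39 lists). The filter of 50 counts left 8 MHC class I genes, with a median of 0.50.

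The complement, microglia and reactive astrocyte lists were also higher in old mice by camera's preset test, but not with an estimated correlation, where the adjusted p = 0.164 for complement, 0.238 for both microglia lists and 0.290 for reactive astrocyte genes. All 16 complement genes had positive log2 fold changes, with a median of 1.22, and 11 passed adjusted over the list alone, against 1 (C3) over all genes. C1qa and C1qb, subunits of the initiating C1q complex, had values of 1.47 ± 0.28 and 1.28 ± 0.25, and C3ar1, the C3a receptor, 1.26 ± 0.25. All 20 microglia identity markers were positive, with a median of 0.70, and 13 passed adjusted over the list alone but none over all genes. Among them were Trem2, a lipid-sensing receptor, at 1.23 ± 0.23 and Ctss, the protease cathepsin S, at 1.24 ± 0.23. All 17 activated microglia genes were positive, with a median of 0.99, and 10 passed adjusted over the list alone, against 2 (Itgax and Cd52) over all genes. Tlr2, a toll-like receptor, stood at 1.70 ± 0.31 and Lyz2, a lysozyme of myeloid cells, at 2.04 ± 0.36. The filter of 50 counts left 8 activated microglia genes, with a median of 0.28.

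Of 15 reactive astrocyte genes, 14 were positive, with a median of 0.59, and 4 passed adjusted over the list alone, namely Gbp2 at 1.39 ± 0.29, Serping1 at 0.55 ± 0.12, C4b at 1.89 ± 0.42 and Serpina3n at 1.57 ± 0.45. None passed over all genes. Serping1 and C4b also stand in the complement list, and Gbp2 is induced by interferon. All 6 MHC class II genes were positive, with a median of 0.76, and Cd74, H2-Aa and the transactivator Ciita passed adjusted over the list alone but not over all genes, at 1.02 ± 0.36, 1.66 ± 0.61 and 0.36 ± 0.14. Of 22 lysosome genes 15 were positive, with a median of 0.17, and 6 passed adjusted over the list alone but none over all genes. They included Ctss, which is also a microglia marker, Cd68 at 0.99 ± 0.27 and Lamp2, a lysosomal membrane protein, at 0.32 ± 0.09. With an estimated correlation the adjusted p = 0.326 for the class II list and 0.372 for the lysosome list. The class II median was 0.36 without old 4 and 0.26 with the filter of 50 counts, which left too few of its genes for the test, and the reactive astrocyte median 0.39 without old 4 and 0.94 without young 2, and the lysosome median was 0.10 with the choroid plexus score as a covariate.

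The clustered beta protocadherins, adhesion genes that neurons express in combinations, had 1 member past the threshold over all genes. Of 21 tested, 16 were positive, with a median of 0.23, and 8 passed adjusted over the list alone, against 1 (Pcdhb14) over all genes. Pcdhb6, Pcdhb11 and Pcdhb8 had log2 fold changes of 0.89 ± 0.16, 0.80 ± 0.16 and 0.61 ± 0.17. The list had an adjusted p = 0.238 with an estimated correlation. Its members are close in sequence, so reads may be shared among them.

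Endothelial, erythroid and choroid plexus markers were higher in old mice by camera's preset test without any member passing, adjusted over the list alone or over all genes. With an estimated correlation the adjusted p = 0.452 for the endothelial and choroid plexus lists and 0.326 for the erythroid list. Of 14 endothelial markers 10 were positive, with a median of 0.20, and Ly6a and Ly6c1 had values of 0.89 ± 0.25 and 0.79 ± 0.26. All 6 erythroid genes were positive, with a median of 0.52, including Alas2, the erythroid haem synthesis enzyme, at 0.51 ± 0.18 and the alpha globin copy Hba-a1 at 1.21 ± 0.38. All 14 choroid plexus and ependymal markers were positive, with a median of 1.07, and Kcnj13 and Calml4 had values of 1.03 ± 0.58 and 0.87 ± 0.35. With the preset correlation, the choroid plexus list was not called without young 4 (adjusted p = 0.0632, median 0.65), nor the endothelial list without old 4 (0.134, median 0.07) or young 3 (0.0784, median 0.12). Both calls held at medians of 0.14 for the endothelial list without young 4, and of 0.60, 1.64 and 1.91 for the choroid plexus list without old 2, old 3 and young 1.

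**Figure D3:**
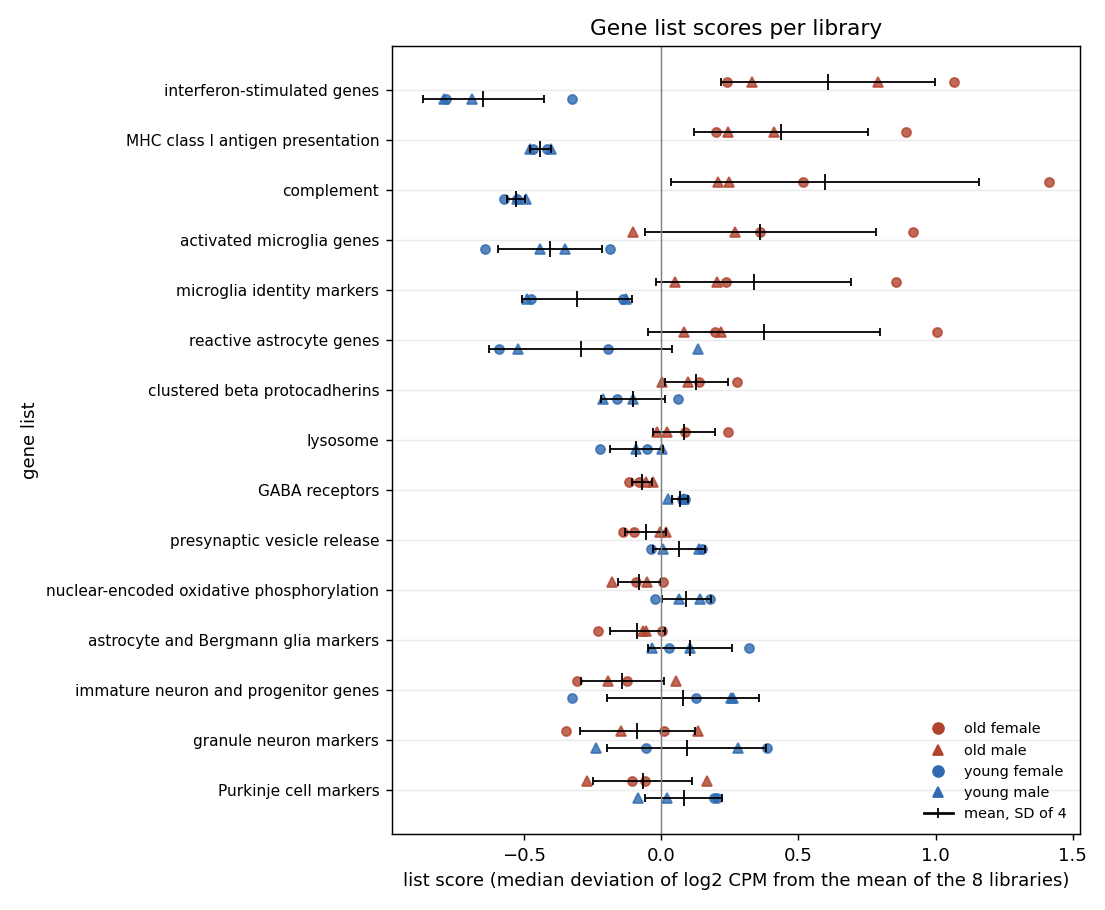
Scores of 15 gene lists per library, as the median deviation of log2 CPM from the mean of the 8 libraries, with 1 point per library (red for old, blue for young, circles for females, triangles for males) and bars for the mean and SD of 4 libraries. Old and young points are apart for the interferon-stimulated, MHC class I, complement, microglia, activated microglia and GABA receptor lists, and old 4 has the highest score in the first 8 lists from the top.

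Lists of synaptic, ion channel and energy metabolism genes were lower in old mice by camera's preset test, with small shifts, at an adjusted p between 0.239 and 0.372 with an estimated correlation. Of 56 nuclear-encoded oxidative phosphorylation genes 50 had negative log2 fold changes, with a median of -0.18, and none passed, adjusted over the list alone or over all genes. The ATP synthase subunit Atp5o had a value of -0.41 ± 0.11 and the cytochrome oxidase subunit Cox5b -0.44 ± 0.12. Of 21 presynaptic vesicle release genes 19 were negative, with a median of -0.15, and none passed. The synaptic vesicle protein Sv2a was at -0.24 ± 0.07. Of 14 GABA receptor genes 12 were negative, with a median of -0.14, and Gabbr1, a subunit of the metabotropic receptor, passed adjusted over the list alone at -0.28 ± 0.08, while Gabra2 had -0.50 ± 0.17. Among 27 glutamate receptor and scaffold genes 23 were negative, with a median of -0.10 and none past the test, including the scaffold Dlg4 at -0.25 ± 0.08. Of 23 voltage-gated and potassium channel genes 19 were negative, with a median of -0.10, and the calcium channel Cacna1e passed adjusted over the list alone at -0.38 ± 0.08, while Kcna1 had -0.24 ± 0.09. No member of these 5 lists passed over all genes. With the preset correlation the glutamate receptor list was not called without old 2 (adjusted p = 0.0501, median -0.10), without young 3 (0.179, median -0.05) or with the choroid plexus score as a covariate (0.091, median -0.07), and the GABA receptor list had medians of -0.09 without old 3 and without old 4. The presynaptic median was -0.09 with the granule neuron score as a covariate, and without old 2, old 3 and young 4 the glutamate receptor median was -0.15 and the GABA receptor median -0.09.

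The granule neuron, Purkinje cell and astroglia lists were also lower by camera's preset test, at an adjusted p between 0.452 and 0.662 with an estimated correlation, while the interneuron list did not pass. Of 15 astrocyte and Bergmann glia markers 13 were negative, with a median of -0.16, and 2 passed adjusted over the list alone, Fabp7 and the acyl-CoA synthetase Acsbg1 at -0.47 ± 0.09, against 1 (Fabp7) over all genes. Hopx, a Bergmann glia marker, had -0.35 ± 0.13. Of 15 Purkinje cell markers 14 were negative, with a median of -0.17, and Gng13, a G protein subunit, passed adjusted over the list alone at -0.41 ± 0.09, while the glutamate transporter Slc1a6 had -0.39 ± 0.15. Of 14 granule neuron markers 13 were negative, with a median of -0.15, and none passed, with Slc17a7, the vesicular glutamate transporter, at -0.37 ± 0.17 and Rbfox3 at -0.27 ± 0.15. The granule list was not called, with the preset correlation, without old 1 (adjusted p = 0.066, median -0.12), old 4 (0.528, median -0.04), young 1 (0.0935, median -0.12) or young 4 (0.788, median -0.01). Neither the granule nor the Purkinje list was called with the choroid plexus score as a covariate (0.319 and 0.091, medians -0.07 and -0.10). With the call kept, the granule median was -0.24 without old 3 and -0.27 without young 2, the Purkinje median -0.10 without old 1, -0.285 without old 3 and -0.10 without young 3, and the astroglia median -0.10 without old 2 and -0.07 without young 3.

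Of 11 immature neuron and progenitor genes 9 were negative, with a median of -0.29, and 2 passed adjusted over the list alone, the tubulin Tubb2b at -0.46 ± 0.11 and the cyclin Ccnd1 at -0.35 ± 0.09. Of 20 immediate early genes 14 were negative, with a median of -0.24, and 2 passed adjusted over the list alone, the activity-induced transcription factors Egr1 at -0.49 ± 0.11 and Egr3 at -1.42 ± 0.38. Of 31 proteasome genes 25 were negative, with a median of -0.12, such as Psmb5 at -0.35 ± 0.10 and Psmd7 at -0.25 ± 0.07. Of 15 heat shock and chaperone genes 12 were negative, with a median of -0.14, such as Hsph1 at -0.35 ± 0.11 and Hsp90ab1 at -0.22 ± 0.08. Of 24 cholesterol synthesis genes 19 were negative, with a median of -0.16, such as Ebp at -0.28 ± 0.12 and Srebf2 at -0.18 ± 0.08. No proteasome, chaperone or cholesterol gene passed adjusted over its list alone, and no gene of these 5 lists passed over all genes. Their adjusted p lay between 0.326 and 0.452 with an estimated correlation. With the preset correlation the immediate early list was not called without old 1 (adjusted p = 0.0612, median -0.15) or old 2 (0.159, median -0.12), the chaperone list without old 1 (0.241, median -0.08) and the cholesterol list without old 3 (0.207, median -0.12), while the immediate early list stayed past it at medians of -0.39 without old 4 and -0.15 without young 1. The chaperone list stayed past it at medians of -0.075 with the choroid plexus score as a covariate and -0.22 without old 2, old 3 and young 4.

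Of the 39 lists tested, 25 passed camera's preset test, 12 higher and 13 lower in old mice, none passed with an estimated correlation, and none passed by fry's directional test (smallest adjusted p = 0.0679, 9 lists at an unadjusted p under 0.05). By fry's test for change in either direction 4 lists passed, the beta protocadherins, interferon-stimulated genes, MHC class I genes and complement genes (adjusted p = 0.000753, 0.029, 0.029 and 0.0385).

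The genes that write, bind or remove DNA methylation and hydroxymethylation, the marks named in the study's title, showed no difference past the test between the ages. None of the 21 tested members passed, adjusted over the list alone or over all genes, 10 were positive and 11 negative, and the list's median was 0.00 (camera adjusted p = 0.445). The 5-methylcytosine dioxygenases Tet1, Tet2 and Tet3 had log2 fold changes of -0.07 ± 0.09, 0.10 ± 0.08 and -0.10 ± 0.10, and Tet3 had 206 ± 14.6 CPM (SD, n = 4) in old and 221 ± 29.1 CPM (SD, n = 4) in young mice. The methyltransferases Dnmt1, Dnmt3a and Dnmt3b were at -0.13 ± 0.10, -0.18 ± 0.10 and 0.00 ± 0.24. Methyl-CpG binding proteins were at 0.02 ± 0.08 for Mbd1, 0.12 ± 0.13 for Mbd2, -0.28 ± 0.08 for Mbd3 and -0.05 ± 0.12 for Mbd4. Uhrf2 was at 0.01 ± 0.10, and the repair genes Tdg, Smug1 and Apex1 were at 0.08 ± 0.14, 0.01 ± 0.12 and -0.15 ± 0.13. Gadd45a and Gadd45b were at -0.26 ± 0.12 and -0.19 ± 0.17. Genes of 2-oxoglutarate and 2-hydroxyglutarate metabolism were at 0.04 ± 0.19 for Idh1, 0.21 ± 0.10 for Idh2 and 0.23 ± 0.13 for D2hgdh. Members near 0, Dnmt3b, Idh1 and Uhrf2 among them, changed sign under other settings. In simulated data of this depth the test recovered 40.3% of genes changed 1.5-fold and 76.1% of genes changed 2-fold by age.

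The other lists did not pass camera's preset test in the model with age and sex and all 8 libraries. Cerebellar interneuron markers had a median log2 fold change of -0.07, mature oligodendrocyte and myelin genes -0.12, oligodendrocyte precursor markers 0.02, pericyte and smooth muscle markers -0.04 and meningeal fibroblast markers 0.18. Cytosolic ribosomal protein genes had a median of -0.03, splicing factors 0.01, circadian clock genes 0.03, unfolded protein and integrated stress response genes 0.06, and senescence and p53 target genes 0.09. Collagens and extracellular matrix genes and proliferation genes had medians of 0.00. Brainstem neuron markers had a median of 0.43 over 7 genes, with members on both sides of 0 and a mean of 0.02, and for the oligodendrocyte precursor list the mean of -0.08 and camera's direction were opposite in sign to the median. Without 1 library the myelin genes passed without old 4, young 1 or young 4 (medians -0.22, -0.17 and -0.22), the interneuron, oligodendrocyte precursor and matrix lists without young 4 (-0.15, -0.10 and -0.15), and the meningeal list without old 2, old 3, young 2 or young 3 (0.24, 0.28, 0.34 and 0.36). The ribosomal list passed without old 2, old 3 or young 3 (-0.03, -0.07 and -0.06), the clock genes without old 4 or young 4 (0.04 and 0.08), the stress response genes without old 1 (0.15) and the brainstem markers without old 3 (1.16). With the granule neuron score as a covariate the interneuron, myelin, oligodendrocyte precursor, clock and matrix lists passed (-0.13, -0.24, -0.14, 0.09 and -0.175), and with the choroid plexus score the myelin, brainstem, stress response and clock lists (-0.21, -0.52, 0.12 and 0.08). The clock list also passed with the filter of 50 counts (0.06), and the brainstem and ribosomal lists without old 2, old 3 and young 4 (0.73 and -0.07). Of 19 lymphocyte markers 13 were listed and none had enough counts to be tested, 4 of 9 forebrain neuron markers were tested, too few for a list, and the 13 mitochondrially encoded protein genes were not analysed here.

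Sex was compared in the same fit. Ddx3y, Kdm5d, Eif2s3y and Uty, genes of the Y chromosome, had 228 to 825 counts in each of the 4 libraries labelled male and 0 counts in each of the 4 labelled female. Against the floor of 3 counts per female library, Ddx3y was at least 226-fold higher in males, at 115.7 ± 9.13 CPM (SD, n = 4), Kdm5d at least 135-fold, Uty at least 94.5-fold and Eif2s3y at least 82.8-fold. The X-linked histone demethylase gene Kdm6a, which escapes X inactivation, was higher in females by 0.79 ± 0.11 (SE) on the log2 scale, at 89.4 ± 10.1 CPM in females and 52.2 ± 7.46 CPM in males (SD, n = 4 each). Prl was the sixth gene past the threshold, with 92 counts in females and 1 in males, of which the old females old 2 and old 4 gave 52 and 37. Whether the Prl counts came from cerebellar cells was not tested. Kdm6a was not called with the replicate number as a block, with the GC correction (adjusted p = 0.113), or without old 1 (0.103), old 2 (0.187), young 1 (0.384), young 2 (0.188), young 3 (0.092) or young 4 (0.0574), at log2 fold changes of 0.68 to 0.84. Prl was not called by limma-voom (0.174), without the age term (0.994), with the block or without old 1 (0.103). Its log2 fold changes there were 4.02, 5.90, 6.48 and 6.96, against 5.88 in the main fit. Without old 3, a male, 46 genes passed in place of 6, and no other library left out moved the count by over 1.5 times.

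By camera's preset test 10 lists differed between the sexes, none of them with an estimated correlation, where the adjusted p lay between 0.833 and 0.988. The complement, activated microglia and microglia identity lists were higher in females, with median log2 fold changes of 0.45, 0.41 and 0.28. The highest score in each was that of the female old 4, at 1.41, 0.92 and 0.85, and the complement scores of young mice were -0.52 and -0.57 in females and -0.49 and -0.52 in males. Also higher in females were the interferon-stimulated genes and beta protocadherins at 0.20 and 0.08. The immediate early, immature neuron, chaperone and cholesterol synthesis lists were lower in females, at -0.33, -0.20, -0.19 and -0.19. Brainstem neuron markers were lower in females at -2.36, and their scores were 1.85, 1.35 and 1.83 in the males old 1, young 1 and young 2 but -1.73 in the male old 3, against -1.73 to -0.21 in females.

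Whether age acted differently in females and males was tested as the interaction of both terms. No gene passed by edgeR's quasi-likelihood test, with 326 genes at an unadjusted p under 0.05 and a smallest adjusted p near 1. DESeq2 gave 1 gene, Mfrp, named after its value was seen, whose interaction by edgeR was 3.08 ± 0.77 (SE) with 2 animals per age and sex. Without old 1 or without old 3, 2 genes passed, and Prlr, the prolactin receptor and a member of the choroid plexus list, was among them both times. In each of these fits 1 old male remained and was taken to vary like the other groups, and old 3 had the lowest choroid plexus score of the 8 libraries. Within males alone no gene passed for age, and within females only Prl did. In simulated data 28.4% of genes with a 2-fold and 75.8% with a 4-fold interaction were recovered, with 76 genes called. No gene was called in the real libraries, so these shares may be too high for them.

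Nnt, the nicotinamide nucleotide transhydrogenase gene whose partial deletion separates C57BL/6J from C57BL/6N mice, was examined because the strain label joins both substrains. It had 11.7 ± 1.62 CPM (SD, n = 4) in old and 8.99 ± 0.970 CPM (SD, n = 4) in young mice, a log2 fold change of 0.39 ± 0.16 that did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.407).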

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

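The tests of GC content, single libraries, microglia, blood, choroid plexus and the second liver sum were chosen only after the results they bear on were seen, while the splits of the libraries and the first liver sum were set before. Gaps within a group of 4 libraries were compared with Dixon's 95% critical value for named genes, list scores, totals and detected genes. Of 264 groups 13 exceeded it, against about 13.2 expected by chance.

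Old 4, from the mouse of 102 weeks, lay apart on the high side for H2-K1 (gap 0.890 of the range), C1qa (0.912), C1qb (0.838), Pcdhb6 (0.871) and the reactive astrocyte score (0.855). Old 1 lay apart on the low side for the cytosolic ribosomal protein score (0.959) and Gabra2 (0.841), and on the high side for the cholesterol synthesis score (0.839). Old 3 lay apart for Calml4 (0.961, low) and the glutamate receptor and scaffold score (0.834, high), and old 2 for Ccnd1 (0.833, low). Among young libraries, young 4 was low for Fabp7 (0.884) and young 3 high for Acsbg1 (0.842).

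From splits of the libraries alone, chance cannot be excluded for the counts of calls. Of the 34 splits of the 8 libraries into 4 and 4 that could be fitted with a term for sex, 2 gave 17 or more genes, the real split of old from young included, and the highest of the others gave 165. For sex, with a term for age, 2 of 34 splits gave 6 or more genes, and the highest of the others gave 444. The 4 Y-linked genes among those 6 had 228 to 825 counts in each male library and 0 in each female one, which argues against chance for these 4. For the gene lists 5 of 34 splits gave 25 or more, and the highest of the others gave 26. Some of these set old 1, old 2 and old 4 with 1 young library, at 25 or 26 lists, and so carry part of the age difference. The split of old 1, old 4, young 1 and young 2 from the rest, balanced for age, gave 26. No fitted split gave fewer than 10 lists, so a call by camera's preset test does not by itself set old apart from young. The split with 165 and 444 genes set old 1, old 4, young 2 and young 3 against the rest, and it points to a structure of the samples that crosses age and sex. The granule neuron scores of old 1, old 4, young 2 and young 3 were -0.15, -0.35, -0.24 and -0.06, and their meningeal fibroblast scores were 0.43, 0.36, 0.39 and 0.38. In old 2, old 3, young 1 and young 4 the granule neuron scores were 0.01, 0.14, 0.28 and 0.38, and the meningeal fibroblast scores -0.11, -0.16, -0.34 and -0.73. With the granule neuron score as a covariate 154 genes passed for age.

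The first pattern is the higher level of interferon-stimulated and MHC class I genes in old mice, with a median log2 fold change of 1.09 over 40 genes. A GC content trend between libraries as the whole cause is argued against by a median of 1.11 after the GC correction, and 1 deviating library by a lowest median of 0.94 with each library left out in turn. More microglia in the old tissue stays open. The score of these genes shifted by 0.44 more than that of the microglia markers, with an exact permutation p of 0.0571, so a rise within cells and a larger share of microglia cannot be told apart here, and 6 of the 20 microglia markers stand in another list. Age itself stays open too, as the design's own explanation, untested apart from these.

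The second pattern is the liver transcripts in old 2, old 3 and young 4, for which no biological explanation was tested. RNA or reads from liver are a candidate source. The sum of 29 further liver genes was at 84.0 CPM in the lowest of the 3 libraries, below the highest of the other 5 at 98.8 CPM, but Itih3, which the cerebellum expresses, made up 61.2% to 86.6% of it in each library, so this sum decides nothing. Over the 24 of these genes averaging under 1 CPM, the lowest of the 3 libraries was at 6.77 CPM and the highest of the other 5 at 5.54 CPM. This is the order that liver RNA would give. The 2 sums rest on 49 counts in young 4 and 34 in old 1, and their counting error was not computed, so the gap between these 2 libraries is not decisive. For old 3 and young 4, blood is argued against by erythroid scores of -0.22 and -0.51, and choroid plexus by scores of -1.73 and -1.68, the 2 lowest of the 8, while both stay open for old 2, with an erythroid score of 0.14 and the highest choroid plexus score, 1.97.

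The third pattern is the higher choroid plexus list in old mice. An uneven share of choroid plexus within both ages is a candidate explanation, since the score ranged over 3.71 within the old group, against a difference of 0.93 between the ages (exact permutation p = 0.40). The call by camera's preset test was lost in 1 of the 8 fits with a library left out, the one without young 4 (median 0.65, adjusted p = 0.0632). The lowest median was 0.60, without old 2, with the call kept. For the first pattern the size of the median was judged and not the call, so dependence of the shift on 1 library is not settled here. A change of choroid plexus transcripts with age stays open and was not tested apart from these.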

How the results depend on the processing

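The alternatives with covariates or a GC correction, and the fit without old 2, old 3 and young 4, were added after seeing the data. The age count of 17 genes became 125 by DESeq2, 1 by limma-voom (Pcdhb14), 26 with the older edgeR dispersions, 62 with 1 surrogate variable, 103 with age in weeks, 9 with the choroid plexus score, 154 with the granule neuron score, 184 without old 2, old 3 and young 4, and 0 to 63 with 1 library left out. It was 12 to 24 with DESeq2 size factors, either filter, no sex term, the fold minimum and the GC correction. The 17 genes kept their direction in each setting that tested them, which is no independent support because they were selected on these same libraries. Of them 17 passed by DESeq2, 16 with the granule neuron score, 15 with the surrogate variable, 6 with the choroid plexus score, 7 without old 4 or young 2, 2 without old 1 or young 1 and none without young 3 or young 4. The sex count of 6 stayed within 4 to 9 except for 46 without old 3, with 4 to 46 over the libraries left out. The interaction count of 0 became 1 by DESeq2 and 0 to 2 with 1 library left out. The list count of 25 became 0 with the estimated correlation and was 23 to 29 otherwise. The cause of these changes was not tested.

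The replicate numbers do not pair the libraries. Same-numbered libraries correlated at 0.156, -0.222, -0.048 and -0.252 in their deviations from the group means, no old library correlated best with the young library of its own number, and numbers 2 and 3 join opposite sexes. With the replicate number as a block, 1 gene passed for age (C3), 4 for sex, 0 for the interaction and 25 lists.

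Genes near a log2 fold change of 0 changed sign, none of them past the threshold in any of these fits, and the cause was not tested. Dnmt3b was at -0.0028 by DESeq2 and -0.0084 with the older dispersions. With the surrogate variable Dnmt3b and Idh1 were at -0.031 and -0.076. With the GC correction Uhrf2 and Idh1 were at -0.0043 and -3e-04. With the choroid plexus score Dnmt3b and Idh1 were at -0.086 and -0.086, and with the granule neuron score Mbd4 and Idh1 were at 0.022 and -0.086. Without old 2, old 3 and young 4, Dnmt3b, Uhrf2, Tdg, Mbd1, Mbd2 and Smug1 were at -0.121, -0.092, -0.029, -0.045, -0.0043 and -0.0079. With 1 library left out, Dnmt3b ranged from -0.085 to 0.11, Uhrf2 from -0.060 to 0.089, Mbd1 from -0.016 to 0.054, Mbd4 from -0.12 to 0.029, Idh1 from -0.11 to 0.17 and Smug1 from -0.058 to 0.077.

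Of the other values of the named genes over these settings, 1724 kept direction and side of the threshold, 148 lost the threshold and 84 gained it. The 1724 include genes that passed neither in the main fit nor in the other setting. Only genes past the threshold could lose it, so 148 against 1724 does not measure how stable the calls are. Of the list medians 612 stayed on their side of the threshold, called or not, while 18 lost the call and 29 gained it. At 6079485 to 7236720 counts per library, 1.5-fold changes by age were recovered for 40.3% of simulated genes, a share that may be too high for the real libraries.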

Other observations

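The gene families below were chosen after their values were seen, so neither their counts nor their medians are independent evidence, and some members (Gbp2, Gbp3 and Tlr2) also stand in the lists above. All 8 tested guanylate-binding proteins, interferon-induced GTPases that act on intracellular pathogens, had positive log2 fold changes, with a median of 1.04, and 6 passed adjusted over the family alone, against 1 (Gbp5) over all genes. All 6 genes of the Irgm, Igtp, Tgtp and Iigp1 group passed adjusted over the family alone, with a median of 1.07, and 2 (Igtp and Irgm1) over all genes. All 7 tested toll-like receptors passed adjusted over the family alone, with a median of 1.29, and none over all genes. Of 5 Schlafen genes 4 passed adjusted over the family alone, with a median of 1.53, and of 5 Fc receptor genes 2 did, with a median of 0.79, and in both families none over all genes.

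Of 20 gamma protocadherins 17 were positive, with a median of 0.23, and 9 passed adjusted over the family alone, against 1 (Pcdhgb4) over all genes. Of 13 alpha protocadherins 11 were positive, with a median of 0.26, and 1 passed adjusted over the family alone but none over all genes. Members of each cluster share 3' exons, so their values are not independent. Of 8 Cbx genes, which encode chromodomain proteins of polycomb complexes and heterochromatin, 5 were negative, with a median of -0.25, and 3 passed adjusted over the family alone but none over all genes.

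The growth hormone gene Gh, like Prl a gene of the anterior pituitary, had 69 counts in old 1, 12 in old 2, 9 in old 4 and 0 or 1 in the other 5 libraries. The serotonin synthesis gene Tph2 had 118 counts in old 1, 66 in young 2 and 3 to 11 in the others, and the noradrenaline transporter gene Slc6a2 had 250 in young 1, 132 in young 2, 128 in old 1 and 1 to 51 in the others. Old 1 had counts for 16975 genes, 84 of them in no other library, against 16239 to 16653 genes in the others. Across genes, the correlation (Spearman) of transcript GC content with a library's deviation in log2 CPM ran from -0.288 in old 2 to 0.429 in young 1, and genes are not independent replicates.

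A hypothesis, tested after the signed medians of these marker lists were seen, was that marker genes of cerebellar neurons change less with age than other genes of the same expression. The median absolute log2 fold change of 41 granule, Purkinje and interneuron markers was 0.117, against 0.0884 for the median of 10000 random lists matched on mean expression, which put it at the 95.4th percentile. The signed median of these genes, -0.107, was already larger in size than the 2.5th percentile of the random lists, 0.0581, so the test could not have favoured the hypothesis and decides nothing.

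A second hypothesis, tested after the gene length trend of single libraries was seen, was that long genes lose expression with age. The mean correlation across genes of gene span with the deviation of log2 CPM was 0.037 in old and -0.036 in young libraries, a difference of 0.073 in the opposite direction (exact permutation p = 0.514). No loss of long genes with age was found.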
